A study of Montastraea cavernosa with 311 samples.

How the data were processed

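Tag-based RNA sequencing (3' tags) was done on 311 libraries of the coral Montastraea cavernosa with its Cladocopium symbiont. The authors deposited raw counts per isogroup and library, host and symbiont isogroups in one table, together with a lookup table that gives 1 gene name per isogroup as text and that the design text ties to UniProt. Per the labels, each library has a site and a depth or arm, and the experiment's libraries a time label. The aligner, read filters and duplicate removal are not given in the sources used here. Every value is a whole number, 1 column without a name is empty, and all 311 libraries were matched to a column. The table holds 31276 isogroups, 17901 of the host and 13375 of the symbiont, and 18668 have a name.

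Groups were taken from the site, depth and time labels. Title tags that recur between a library without a time label and timed libraries were read as colonies, which gave 26 baseline libraries. Library numbers were divided into barcode runs, stretches in which no barcode pair repeats, as an inferred library batch. CBC and PRTER have runs of their own, and the month and year in a title were read as a collection campaign, X-14 as October of that year. Host and symbiont isogroups were analysed apart, each scaled within its own library total. Libraries under 20000 counts in the compartment were left out, which kept 253 natural and 69 experiment libraries for the host and 103 and 13 for the symbiont. Totals ranged from 2649 to 1211111 per library. No interval or floor for single-library shares is given. It is not known here whether duplicates were removed, and such intervals would cover counting error alone.

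The tests, gene lists, naming rule and a first set of alternatives were fixed before the data were examined. In that design edgeR 4.0.16 (R 4.3.3) fitted robust quasi-likelihood models to counts with TMM scaling and filterByExpr, at a Benjamini-Hochberg adjusted p of 0.05. Natural libraries had 1 mean per site and depth, with contrasts of mesophotic minus shallow over the 4 sites and in each, an F test of depth by site, an F test between sites, and EFGB minus WFGB. Experiment libraries had 1 mean per arm and time plus site, with transplants compared with either control at times 6 and 12, the change from baseline beyond that of mesophotic controls, and the arms at baseline. The share of symbiont counts was compared as log2 odds with 2-sided permutation tests within sites (100000 resamples, or exact where a group had fewer than 10 libraries), adjusted over each family. The depth score was the mean log2 CPM of isogroups called higher in shallow natural libraries outside the experiment minus that of isogroups called higher in mesophotic ones, all with the same sign at the 4 sites. Its change from baseline was compared by an exact permutation test within sites. The 21 host and 17 symbiont lists were matched by words in the gene names and tested with camera (correlation 0.01, and again with an estimated correlation) when at least 5 members were tested. The host lists were fluorescent proteins, heat shock proteins and chaperones, antioxidants, innate immunity, calcification, extracellular matrix, circadian clock and photoreception, DNA repair, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome and ubiquitin, apoptosis, lipid metabolism, symbiont nutrient and sterol exchange, glycolysis, and markers of germ line, nematocytes, neurons, mucus and gland cells, cilia, and muscle and actin cytoskeleton. The symbiont lists covered photosystem and electron transport, light harvesting, carbon fixation, chlorophyll and heme synthesis, carotenoid and xanthophyll metabolism, antioxidants, heat shock proteins and chaperones, nitrogen and phosphate uptake, cytosolic ribosomal proteins, oxidative phosphorylation, photoreceptors, sugar and organic transporters, flagella and motility, cell cycle, starch and lipid storage, proteasome and ubiquitin, and transposon and reverse transcriptase genes.

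Genes were named by a rule. For the mean over sites it took the 6 largest log2 folds each way among isogroups with an informative name, past the threshold, with a mean log2 CPM of at least 3 and the same sign at all 4 sites. From each list it took the member with the smallest p each way, and for each other comparison the 3 largest folds each way. Genes given with limma values were named after their values had been seen.

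A second model was added after the data had been seen. limma 3.58.1 (trend and robust options) was fitted to log2 CPM (prior count 2, library-size scaling) of isogroups detected in at least 10% of libraries, with or without the log2 number of detected isogroups as a covariate. It was chosen because edgeR had called about as many isogroups with reassigned labels as with the real ones, and after limma with TMM, voom weights and a model of detection had been looked at. Its folds understate those of isogroups with low counts. Both were tested on simulated data after the real fits, with 200 host isogroups changed. edgeR called 262, of which 128 (48.9%) were false, and recovered 25.3%, 84.6% and 100% of the 2-, 4- and 8-fold changes, and limma called 81, of which 1 (1.24%) was false, and recovered 9.33%, 49.2% and 68.3%. For the symbiont edgeR called 117 with 47 false and limma 2 with 0 false, and at time 12 in the experiment both called 0. The simulated host depth comparison gave both models the 3703 isogroups of the edgeR filter. Beyond library totals and TMM factors, the simulated libraries carried no difference between collections. False calls from collection or library complexity in the real data could thus not be measured for either model. edgeR remained the test of record because the design had fixed it.

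Alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, no filter, all libraries, a minimum of 100000 counts, barcode run or campaign as covariates, each site alone, WFGB alone, a block for colony, leaving out each timed library, the share in percent or in larger libraries, an estimated correlation for lists and the 100 top genes each way for the score. Those added later were the limma models, a minimum of 5000 symbiont counts, counts capped at the 90th percentile of detected values, leaving out the X-14 libraries, camera on the limma fit, a wider ribosomal list, limma genes for the score, the change of share from baseline, its values without each colony, and the log2 library total as a covariate. RLE minus TMM moved the median log2 difference of host isogroups by -0.03 for the mean over sites, -0.19 at WFGB, -0.47 at EFGB, 0.32 at PRTER, 0.27 at CBC and -0.37 for EFGB minus WFGB, and in the experiment by 0.23, 0.01 and -0.10 at time 6 (against mesophotic controls, against shallow controls and in the change), by -0.71, -0.34 and -1.03 at time 12 and by 0.32 at baseline. No gene named by the rule and called under either scaling changed sign between the 2 scalings. Calls were also counted in 100 regroupings with a fixed seed, the real one included. These reassigned depth labels within sites, site labels within depths, or the arms of whole colonies within sites. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 did the other computations.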

Results

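The series counted 3' RNA tags of the reef coral Montastraea cavernosa, the host, and of its algal symbiont, a dinoflagellate of the genus Cladocopium. Natural colonies at 4 sites coded WFGB, EFGB, PRTER and CBC gave 146 libraries from shallow depth and 119 from mesophotic depth, the dim zone below the shallow reef. There were 33 mesophotic and 36 shallow libraries at WFGB, 21 and 41 at EFGB, 41 and 31 at PRTER, and 24 and 38 at CBC. Another 46 libraries belonged to an experiment at WFGB and EFGB with transplants, mesophotic controls and shallow controls. Its times are labelled 6 and 12, spelled out in the labels, which give no unit. At time 6 there were 8 transplants, 7 mesophotic controls and 10 shallow controls, and at time 12 6, 6 and 9. Title tags linked 26 of the natural libraries to these colonies as their baselines, and the baselines of transplants carried the mesophotic label. Titles of time 12 libraries carry the date IX-16 and those of time 6 V-16, except that EFGB_transplant_six replicates 1 and 2 carry IX-16 and their baselines V-16, where the other baselines have coded titles. Arm and collection are thus partly mixed at time 6. A library held a median of 140660 counts (at most 1211111), of which the host took a median of 126640 and the symbiont 12628. Counts are per isogroup, a cluster of transcripts treated as a gene, and a library had counts for a median of 12.6% of the 17901 host isogroups and 2.31% of the 13375 symbiont isogroups. The most abundant host isogroup took a median of 5.41% of a library's host counts, and the most abundant symbiont isogroup 20.9% of its symbiont counts. Ribosomal protein L6 (Mcavernosa17045) was the top host isogroup in 37.3% of libraries and a sea anemone cytotoxic protein (Mcavernosa18854) in 15.1%. Phosphoglycerate mutase (Cladocopium275455) was the top symbiont isogroup in 44.7%.

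The design text asks how shallow and mesophotic colonies differ at each site, and the share of counts from the symbiont is the broadest such measure. At PRTER the symbiont took a median of 20.1% of the counts of mesophotic libraries and 10.8% of those of shallow libraries. The difference in log2 odds was 1.05 ± 0.18 (SE, n = 41 and 31), with an adjusted permutation p of 5e-05, the smallest that 100000 resamples over 5 tests can give. It was 1.28 ± 0.22 (permutation p = 1e-05, the smallest possible, n = 20 and 17) within barcode run 2, a stretch of library numbers without a repeated barcode. Within run 3 it was 0.82 ± 0.29 (permutation p = 0.00609, n = 21 and 14). Within the libraries whose titles carry the date VIII-13 it was 0.12 ± 0.40 (exact permutation p = 0.663, n = 22 and 5), and among those with coded titles 1.29 ± 0.23 (permutation p = 1e-05, n = 19 and 26). The difference was 0.35 ± 0.26 at WFGB (adjusted permutation p = 0.223, n = 33 and 36), -0.44 ± 0.22 at EFGB (0.0949, n = 21 and 41) and 0.24 ± 0.23 at CBC (0.286, n = 24 and 38). Within the barcode runs it ranged from 0.00 to 0.91 at WFGB, highest in run 5 (exact permutation p = 0.0182, n = 8 and 4), and from -0.79 in run 6 (exact permutation p = 0.00749, n = 5 and 9) to 0.35 at EFGB, while CBC was a single run. Among coded titles it was -0.98 ± 0.54 at EFGB (exact permutation p = 0.0248, n = 16 and 5) and 0.41 ± 0.43 at WFGB (permutation p = 0.321, n = 26 and 12). Within V-16 at EFGB it was -0.31 ± 0.40 (exact permutation p = 0.431, n = 4 and 10). The mean over sites was 0.30 ± 0.11 (adjusted permutation p = 0.0231, n = 119 and 146), and the depth differences themselves differed between sites (F = 7.53, permutation p = 9.0e-05). The mean lost its call among the libraries with at least 100000 counts, where it was 0.20 (adjusted permutation p = 0.367, n = 71 and 77). It also did so without the libraries whose titles carry X-14, all of them shallow, where it was 0.29 (adjusted permutation p = 0.0814, n = 119 and 98).

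**Figure D1:**
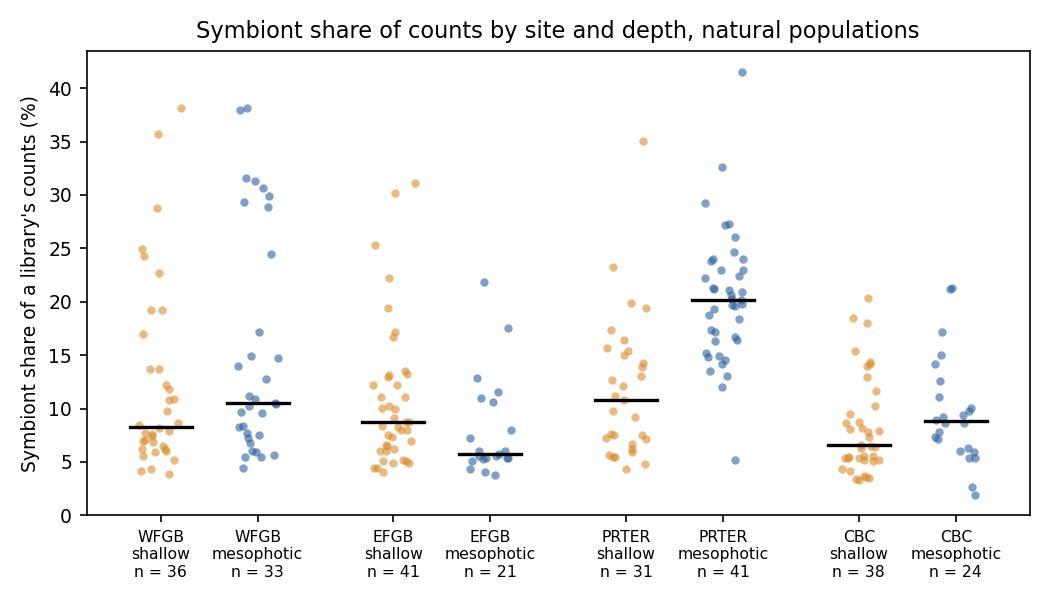
Share of a library's counts that came from Cladocopium isogroups (percent) in the natural libraries of each site and depth, with 1 dot per library and black lines at the medians. At PRTER the median was 20.1% at mesophotic and 10.8% at shallow depth.

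Averaged over the 4 sites, most host genes that passed the limma test had lower transcript levels in mesophotic than in shallow colonies, but this lean was lost with a covariate and without the X-14 libraries. The ammonium transporter Mcavernosa08187, a membrane channel for ammonia, differed by -1.18 ± 0.23 in log2 CPM (limma, adjusted p = 0.000843, n = 28, 21, 41 and 22 mesophotic and 35, 39, 31 and 36 shallow libraries at WFGB, EFGB, PRTER and CBC). It was detected in 51.8% of the mesophotic and 80.9% of the shallow libraries. Glutathione peroxidase (Mcavernosa23572), which reduces peroxides, differed by -1.42 ± 0.29 (adjusted p = 0.00314). Carbonic anhydrase II (Mcavernosa13573), which interconverts carbon dioxide and bicarbonate, differed by -0.91 ± 0.21 (adjusted p = 0.00707, detected in 38 against 93). The iron-sulfur protein CDGSH iron sulfur domain 2 (Mcavernosa26566) differed by -1.51 ± 0.32 (adjusted p = 0.00369), heme binding protein 2 (Mcavernosa02815) by -0.997 ± 0.22 and the endoplasmic reticulum chaperone Grp94 (Mcavernosa03557) by -1.18 ± 0.28. Among enzymes that repair DNA, a photolyase-like protein (Mcavernosa22577), of a family that repairs ultraviolet damage, differed by -0.59 ± 0.14 (detected in 7 against 36), and NEIL1 (Mcavernosa03883), a glycosylase that removes oxidised bases, by -0.998 ± 0.24. Higher in mesophotic colonies were a gene named myeloid lymphoid or mixed-lineage leukemia (Mcavernosa00617), by 0.74 ± 0.18 (adjusted p = 0.0133, detected in 29 mesophotic and 15 shallow libraries), and a crystallin of the ADP-ribosylation type (Mcavernosa13388), by 0.62 ± 0.14.

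In all, limma, which was chosen after the data had been seen, called 36 of 6629 host isogroups for the mean over sites, 3 higher and 33 lower in mesophotic libraries. With the number of isogroups detected per library as a covariate it called 8 (4 higher and 4 lower), of which 7 were among the 36. The ammonium transporter (adjusted p = 0.00872) and glutathione peroxidase (adjusted p = 0.0213) stayed called and carbonic anhydrase II did not (adjusted p = 0.0514). Without the X-14 libraries limma called 3 (2 higher and 1 lower), the ammonium transporter among them (-1.23, adjusted p = 0.0483). The test fixed in the design, edgeR, called 590 of 3703 host isogroups, 221 higher and 369 lower in mesophotic libraries (5.97% and 9.96% of isogroups, and 5.36% and 4.90% without X-14). It shared 21 calls with limma. With size factors by RLE, edgeR called 355, and 26 of 100 regroupings of the libraries within sites gave at least 590, up to 829. Of its 6 largest increases by the naming rule, the leukemia gene Mcavernosa00617 had 4.34 ± 0.44 (adjusted p = 3.44e-16), the lipid acyltransferase AGPAT6 (Mcavernosa17683) 3.17 and cubilin (Mcavernosa15584), an endocytic receptor, 2.80. The largest decreases were prefoldin (Mcavernosa14418, a co-chaperone) at -3.74, myosin IIIB (Mcavernosa26500) at -3.51, an acyl-CoA dehydrogenase (Mcavernosa11774) at -3.47 and heme binding protein 2 at -3.46 ± 0.52. A single library held 46.9% of the acyltransferase's counts and 78.1% of those of prefoldin, and limma called neither.

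**Figure D2:**
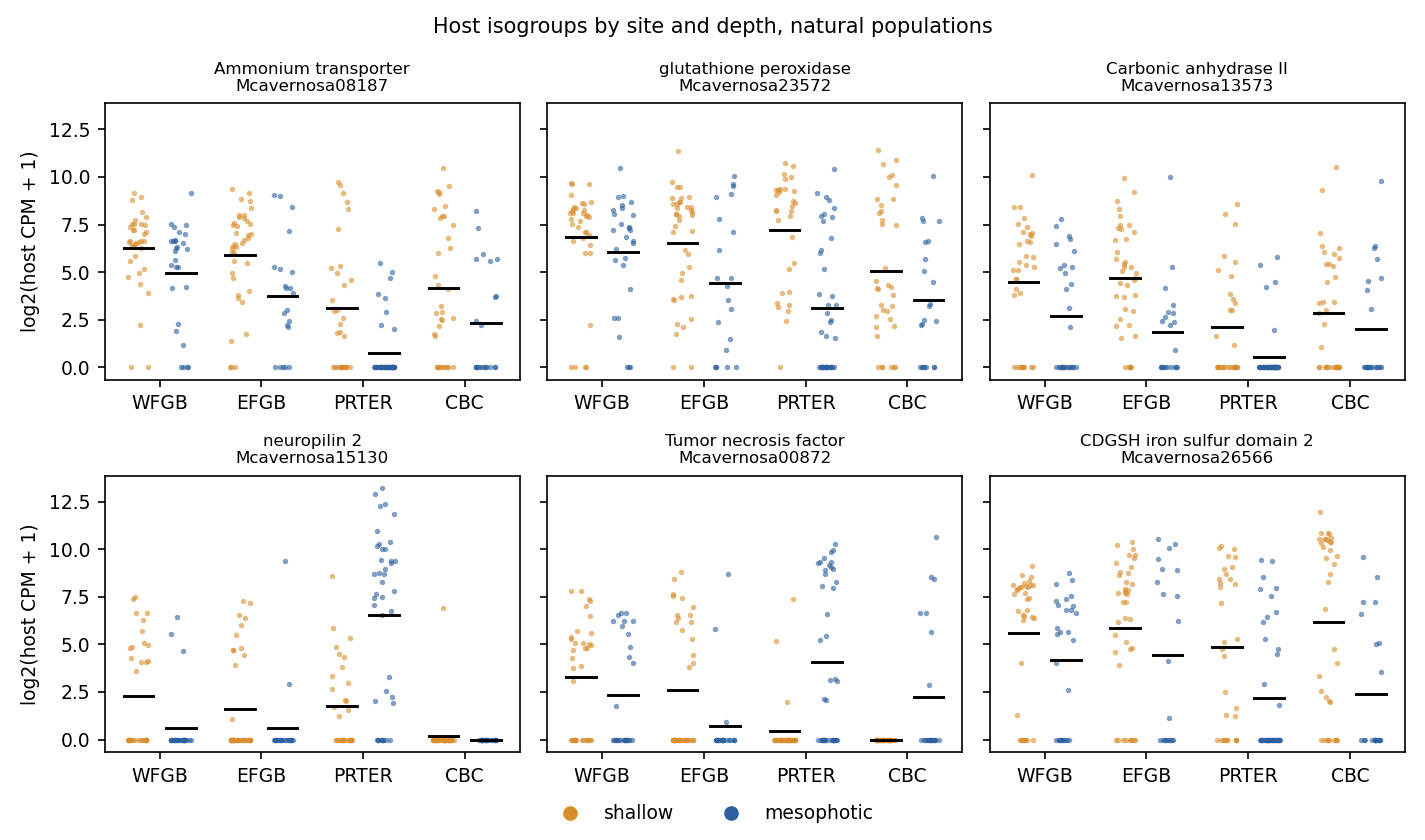
Level of 6 host genes as log2 of CPM plus 1 in the natural libraries with at least 20000 host counts, by site and depth, with 1 dot per library and black lines at the means. Neuropilin 2 was detected in 32 of 41 mesophotic and 15 of 31 shallow libraries at PRTER, and the ammonium transporter in 51.8% of mesophotic and 80.9% of shallow libraries over all sites.

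The gene lists group these calls by process, and the counts that follow are members higher and lower in mesophotic libraries among the members tested by edgeR. Of 16 members of innate immunity, 3 were higher and 0 lower, the first of them a tumor necrosis factor ligand (Mcavernosa00872) at 2.69 ± 0.40 (adjusted p = 4.34e-08). This was the host list that passed the camera test for the mean over sites (median log2 difference 0.46, adjusted p = 0.0158, but adjusted p = 0.444 with an estimated correlation). By contrast limma called 0 of 31 members, with a median of -0.07 (camera adjusted p = 0.0519). In 12 of 100 regroupings at least 1 host list passed. Mucus and gland markers had 0 higher and 5 lower of 11, muscle and actin cytoskeleton markers 2 and 8 of 55, neuron markers 0 and 3 of 8, with synaptotagmin (Mcavernosa06300), a sensor of vesicle release, at -1.38 ± 0.43, and DNA repair 0 and 2 of 10. Germ line markers had 3 and 1 of 17, apoptosis 3 and 1 of 18, proteasome and ubiquitin 3 and 3 of 42, heat shock proteins and chaperones 2 and 1 of 30, and cilia markers 2 and 1 of 18. Antioxidants had 1 and 2 of 19, with glutathione S-transferase kappa 1 (Mcavernosa23156) at 1.53 ± 0.34 and peroxidasin (Mcavernosa10722) at -1.84 ± 0.50, and lipid metabolism 1 and 3 of 33. Symbiont nutrient and sterol exchange had 1 and 1 of 9. The higher one was a nuclear pore protein (Mcavernosa24180) that entered by the letters NPC alone, and the lower one the ammonium transporter. Calcification had 0 and 1 of 6 (carbonic anhydrase II), extracellular matrix 1 and 0 of 6 (hemicentin 1, Mcavernosa04516, at 1.70 ± 0.42), circadian clock and photoreception 1 and 0 of 6, and oxidative phosphorylation 2 and 0 of 12. The member of the clock list is a rhodopsin-family receptor (Mcavernosa06196), and that with the smallest p in oxidative phosphorylation (Mcavernosa25260) is a methylthioribulose-phosphate dehydratase whose name cites cytochrome c. None of 8 cytosolic ribosomal proteins passed, nor any of 70 in a list by the words ribosomal protein that was added later.

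Adjusted over the list alone, the counts differed from these in 6 host lists: heat shock proteins 0 and 1, DNA repair 0 and 3, oxidative phosphorylation 3 and 1, lipid metabolism 1 and 2, nutrient exchange 2 and 1, and cilia 3 and 2. The camera test gave adjusted p of 0.221 or more for the host lists other than innate immunity. Its direction was opposite to the sign of the median for heat shock proteins, apoptosis, nutrient exchange, germ line, cilia and muscle markers. Glycolysis (4 tested, hexokinase Mcavernosa04107 higher at 1.48 ± 0.49) and nematocyte markers (1 tested, a Ras-related toxin substrate, Mcavernosa31324, at 0.26 ± 0.42) were too small for a set test, and no fluorescent protein was tested. Of the smallest-p members named by rule, carbonic anhydrase II and the ammonium transporter were also called by limma.

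At PRTER neuropilin 2 (Mcavernosa15130), a co-receptor for semaphorins, was higher in mesophotic libraries by 3.50 ± 0.39 (limma, adjusted p = 2.62e-13, n = 41 and 31; detected in 32 against 15). Plexin b1 (Mcavernosa09600), a semaphorin receptor, was higher by 1.66 ± 0.42 (adjusted p = 0.022; 17 against 1). The tumor necrosis factor ligand was higher by 2.20 ± 0.41 (adjusted p = 0.000406; 23 against 3), a tyrosine kinase (Mcavernosa17605) by 2.61 ± 0.49, and microsomal glutathione S-transferase (Mcavernosa14920) by 2.52 ± 0.54. A lipoxygenase (Mcavernosa04604) was detected in 11 mesophotic and 0 shallow libraries. Glutathione peroxidase was lower by -2.63 ± 0.54 (adjusted p = 0.00199; 23 against 30) and a chymotrypsin-like protease (Mcavernosa20219) by -2.32 ± 0.56. limma called 40 isogroups at PRTER, 34 higher and 6 lower, and 39 of these again with the detected-isogroup covariate, under which it called 49. edgeR called 757, 368 higher and 389 lower (9.53% and 5.54% of isogroups by RLE), but 6 higher and 37 lower when PRTER was fitted alone. Its largest folds included a DEAD box helicase (Mcavernosa13577) detected in 2 of 41 and 2 of 31 libraries, 98.5% of its counts in a single library.

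At CBC, bcl2-like 1 (Mcavernosa06482), an inhibitor of apoptosis, was higher in mesophotic libraries by 2.71 ± 0.59 (limma, adjusted p = 0.0209, n = 22 and 36), and cytosolic phospholipase A2 (Mcavernosa22551), which releases arachidonic acid, by 1.89 ± 0.43 (adjusted p = 0.0234). A zona pellucida domain protein (ZP, Mcavernosa09214) was lower by -2.68 ± 0.63 (adjusted p = 0.0282), CDGSH iron sulfur domain 2 by -2.64 ± 0.66 and ribosomal protein S18 (Mcavernosa18279) by -1.62 ± 0.41 (adjusted p = 0.0489 for both). limma called 16 isogroups, 8 higher and 8 lower, and 24 with the covariate, the 16 among them, but 0 without the X-14 libraries (371 at an unadjusted p under 0.05, 869 by edgeR), none of which came from CBC. edgeR called 1049, 451 higher and 598 lower (9.34% and 7.86% of isogroups by RLE), and 27 of 100 regroupings gave as many or more. Its largest fold belonged to an ankyrin repeat gene (Mcavernosa00504) detected in 2 of 22 and 1 of 36 libraries.

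At WFGB, bone morphogenetic protein 1 (Mcavernosa31525), a protease of the extracellular matrix, was lower in mesophotic libraries by -1.42 ± 0.25 (limma, adjusted p = 0.000314, n = 28 and 35; detected in 4 against 21), a desaturase (Mcavernosa20744) by -2.28 ± 0.44 and heme binding protein 2 by -1.98 ± 0.43. limma called 38 isogroups, 4 higher and 34 lower (5 of 100 regroupings gave as many), 15 with the covariate and 0 without the X-14 libraries (418 at an unadjusted p under 0.05), where bone morphogenetic protein 1 had -0.46 (adjusted p = 0.694). A median of 3466 host isogroups was detected in mesophotic and 4418.5 in shallow WFGB libraries (log2 difference -0.39, permutation p = 0.0114, n = 33 and 36). edgeR called 84 isogroups higher and 18 lower, but 1 and 3 by RLE, and 2 in all without X-14. Of 8 cytosolic ribosomal proteins at WFGB, 0 passed over all genes and 4 were higher adjusted over the list alone, and as a set they were higher (median 1.35, camera adjusted p = 6.11e-05, adjusted p = 0.0326 with an estimated correlation, 0.0979 on the limma fit). DNA repair was lower as a set there (median -0.67, camera adjusted p = 0.0036, adjusted p = 0.0759 with an estimated correlation), with 0 of 10 past the test over all genes and 1 lower adjusted over the list alone.

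At EFGB the E3 ligase domain gene Mib_herc2 (Mcavernosa04218) was higher in mesophotic libraries by 2.23 ± 0.44 (limma, adjusted p = 0.0013, n = 21 and 39), and stayed called with the covariate (adjusted p = 3.39e-05) and without X-14 (adjusted p = 0.00632). Grp94 was lower by -2.72 ± 0.58 (adjusted p = 0.0027; adjusted p = 0.0849 with the covariate and 0.00437 without X-14), the scaffold protein AHNAK (Mcavernosa26996) by -3.52 ± 0.70 and a ferritin-like iron store (Mcavernosa17019) by -2.88 ± 0.59. AHNAK and the ferritin-like gene lost their calls with the covariate (adjusted p = 0.188 and 0.164) and without X-14 (0.193 and 0.137). limma called 1090 isogroups, 38 higher and 1052 lower, but 5 with the covariate, all higher, and 36 without X-14, 9 higher and 27 lower. A median of 1782 host isogroups was detected in mesophotic and 3570 in shallow EFGB libraries. edgeR called 2.51% of isogroups higher and 6.24% lower (0.324% and 4.10% by RLE), but 11 isogroups higher and 2 lower when EFGB was fitted alone.

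Depth differences were compared between sites with an F test on each isogroup. Neuropilin 2, the gene with the smallest p at PRTER, differed there by 3.50 and at WFGB, EFGB and CBC by -0.76, -0.41 and -0.10 in the limma fit (2.38 at EFGB in edgeR). edgeR called 1598 of 3703 host isogroups for depth by site, limma 412 and limma with the covariate 27, of which 25 were among the 412. Depth labels reassigned within sites gave edgeR a median of 1124 calls.

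Sites were compared over both depths, but only WFGB and EFGB shared barcode runs, so that other site differences cannot be told apart from library batch. Between these 2, leucine-rich repeat kinase 2 (Mcavernosa22235) was lower at EFGB by -0.99 ± 0.18 (limma, adjusted p = 9.67e-05, n = 60 EFGB and 63 WFGB). Milk fat globule-EGF factor 8 (Mcavernosa03829), a bridge between dying cells and phagocytes, was lower by -0.78 ± 0.15 (adjusted p = 0.000123). Both stayed called with the covariate (adjusted p = 0.0184 and 0.0244). limma called 1702 isogroups, 25 higher and 1677 lower at EFGB, and 15 with the covariate. edgeR called 3.16% of isogroups higher and 4.16% lower (0.162% and 2.65% by RLE), and 41 of 100 regroupings gave as many calls or more. Oxidative phosphorylation was higher at EFGB as a set (2 higher and 1 lower of 12 over all genes, 4 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 0.00827, adjusted p = 0.0572 with an estimated correlation). So were the cytosolic ribosomal proteins (0 of 8 over all genes, 1 higher adjusted over the list alone, median 0.51, camera adjusted p = 0.00827, adjusted p = 0.215 with an estimated correlation). On the limma fit the medians of the 2 lists were -0.05 and -0.27. Over all 4 sites edgeR called 2269 isogroups and limma 4787.

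In the symbiont, limma with its main settings called the most isogroups between depths at PRTER, whereas edgeR called more at CBC and EFGB. Most genes called at PRTER with the main settings of limma and edgeR were higher in mesophotic libraries, a lean that other settings did not all share. A repair enzyme of aged proteins, protein-L-isoaspartate O-methyltransferase (Cladocopium210321), was higher by 2.59 ± 0.43 (limma, adjusted p = 1.57e-05, n = 32 and 22; detected in 27 against 6). A core antenna component of a photosystem (Cladocopium226229) was higher by 2.30 ± 0.44 (adjusted p = 0.000215; 18 against 3). A mitochondrial solute carrier (Cladocopium46099) was higher by 3.82 ± 0.78, a sterol reductase of the ERG4/ERG24 family (Cladocopium42888) by 2.09 ± 0.44, phosphoglycerate kinase (Cladocopium191732) by 2.69 ± 0.62 and a gene of thiamine synthesis (Cladocopium234288) by 2.88 ± 0.69. limma called 47 of 714 symbiont isogroups at PRTER, 46 higher and 1 lower, and 29 with the covariate, 24 of them among the 47. edgeR called 85 of 459 there, 69 higher and 16 lower, but 18 each way with all libraries kept, and 1 higher and 2 lower with PRTER fitted alone. DESeq2 called 20 higher and 40 lower, and limma with the covariate and a minimum of 5000 counts 50 each way. At WFGB limma called 34, all lower in mesophotic libraries, where edgeR called 0 (74 at an unadjusted p under 0.05, 36 by DESeq2). The WFGB comparison had 8 mesophotic and 7 shallow symbiont libraries, and without X-14 limma called 2. Of 6 symbiont heat shock proteins and chaperones, 3 were lower there in the limma fit (camera adjusted p = 0.00776), but in 11 of 100 regroupings at least 1 list passed.

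For the symbiont's mean over sites (n = 53 mesophotic and 50 shallow), edgeR called 42 isogroups, 12 higher and 30 lower, among them glutamate-1-semialdehyde aminomutase (Cladocopium41666), an enzyme of chlorophyll synthesis, at 3.15 ± 0.84 (adjusted p = 0.00678; detected in 25 against 11). A monooxygenase (Cladocopium51552) was higher by 4.59 ± 1.06, with 86.4% of its counts in a single library, and an isochorismatase (Cladocopium117437) lower by -5.55 ± 1.22. limma called 2 isogroups, neither of them among these 42, and 33 of 100 regroupings gave edgeR as many or more. Photosystem and electron transport had 0 of 6 members called by edgeR, light harvesting 0 of 6 (1 higher and 1 lower adjusted over the list alone), carbon fixation 0 of 5 and starch and lipid storage 0 of 5, with camera adjusted p of 0.222 or more. The camera direction was opposite to the sign of the median for light harvesting and for starch and lipid storage. At EFGB carbon fixation was higher as a set (0 of 5 called over all genes and adjusted over the list alone, median 3.81, camera adjusted p = 0.0356, adjusted p = 0.0853 with an estimated correlation, 0.0437 on the limma fit, 6 mesophotic and 8 shallow libraries). Chlorophyll and heme synthesis had 1 higher of 1 and cell cycle 2 lower of 2. No member was called among 3 of carotenoid and xanthophyll metabolism (1 higher adjusted over the list alone), 3 antioxidants, 2 heat shock proteins and chaperones, 3 of nitrogen and phosphate uptake, 1 cytosolic ribosomal protein, 2 of oxidative phosphorylation, 2 of flagella and motility or 2 of proteasome and ubiquitin. No photoreceptor, sugar and organic transporter or transposon and reverse transcriptase gene was tested. edgeR called 60 isogroups higher and 46 lower at EFGB, and 31 higher and 120 lower at CBC (86 and 26 without a filter), where limma called 0 (22 at an unadjusted p under 0.05). It called 40.5% of isogroups for depth by site, 73.4% between sites and 16.3% between EFGB and WFGB (14 higher, 61 lower, but 7 and 0 without a filter and 29 and 31 with all libraries kept). The calls at EFGB became 0 with barcode run, with campaign and without X-14 (68, 27 and 20.9% of isogroups at an unadjusted p under 0.05; 73 calls by DESeq2, 1 by limma). Those for the mean became 14, 0 (33) and 4 (78 by DESeq2), and the 75 between EFGB and WFGB became 15 with barcode run. Several of its largest folds at CBC came from 1 library, such as that of a trypsin-like gene (Cladocopium214787) detected in 1 of 7 and 0 of 13.

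The experiment asked how colonies responded over time to transplantation. At time 12, an oxidoreductase named dehydrogenase (Mcavernosa23966) was higher in transplants than in mesophotic controls by 5.39 ± 0.94 in log2 CPM (limma, adjusted p = 0.00081; detected in 5 of 5 against 1 of 6) and than in shallow controls by 5.22 ± 0.86 (adjusted p = 0.00019; 3 of 9). It was the only isogroup limma called in either comparison, edgeR gave adjusted p of 0.0766 and 0.0459, and 30 and 29 of 100 regroupings gave limma at least 1 call. A subunit gene of cytochrome c oxidase (Mcavernosa30572), the last enzyme of the respiratory chain, was higher than in mesophotic controls by 3.33 ± 0.79 (edgeR, adjusted p = 0.0477). A transferrin-domain gene (TR_FER, Mcavernosa02133) was lower by -8.68 ± 2.09 (adjusted p = 0.0477; detected in 2 of 5 against 6 of 6). PR domain containing 6 (Mcavernosa19834) was lower than in shallow controls (edgeR, adjusted p = 0.0459), detected in 0 of 5 transplants and 9 of 9 controls. At time 12 the median number of detected host isogroups at WFGB was 1431 in transplants, 4457 in mesophotic and 3645 in shallow controls. At EFGB it was 2857, 1390 (1 library) and 2301. Arm is thus partly mixed with library complexity at time 12. At time 12 edgeR called 4 isogroups against mesophotic controls (2 higher, 2 lower, with 0.782% and 8.74% of isogroups by RLE). Against shallow controls it called 2.21% of isogroups higher and 6.09% lower, but 0.712% and 0.0776% without a filter. Beyond the change of mesophotic controls from baseline it called 40 higher and 91 lower (37 and 335 by RLE), where limma called 0 (1119 at an unadjusted p under 0.05, 601 with the detected-isogroup covariate) and edgeR with a block for colony 0 (606). Cytosolic ribosomal proteins rose as a set in this last comparison (1 of 8 higher over all genes and adjusted over the list alone, median 1.99, camera adjusted p = 0.0112, adjusted p = 0.098 with an estimated correlation, 0.0361 on the limma fit).

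These counts depended on single libraries. The 8.30% of isogroups called against shallow controls at time 12 became 0 without EFGB_transplant_twelve replicate 2 or EFGB_shallow_twelve replicate 3, 0.179% without EFGB_transplant_twelve replicate 1 and 0.565%, 0.330% and 0.535% without WFGB_transplant_twelve replicates 1, 2 and 3. It became 3.39% without WFGB_shallow_twelve replicate 2 and 0.381% without EFGB_shallow_twelve replicate 2. Apart from WFGB_shallow_twelve replicate 2, leaving out any of these also ended the call of PR domain containing 6. The 4 isogroups called against mesophotic controls became 0 without EFGB_transplant_twelve replicate 1 or 2, any of the 3 WFGB_transplant_twelve libraries, any of the 5 WFGB_mesophotic_twelve libraries or WFGB_mesophotic_six replicate 5, and 1 without EFGB_mesophotic_twelve replicate 1, WFGB_shallow_six replicate 1 or WFGB_shallow_twelve replicate 4 or 5. Each of these ended the calls of cytochrome c oxidase and the transferrin-domain gene. The 3.66% called in the change became 1.15% and 1.07% without EFGB_transplant_twelve replicates 1 and 2, 1.04% and 0.560% without WFGB_transplant_twelve replicates 2 and 3, and 1.99%, 2.29%, 1.95%, 2.06% and 1.73% without WFGB_mesophotic_twelve replicates 1 to 5.

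Genes named by rule at time 6 rested on few detections. Archain 1 (Mcavernosa28396), a coat protein of transport vesicles, was detected in 6 of 8 transplants and 2 of 7 mesophotic controls and was higher in the change from baseline (edgeR, adjusted p = 0.0242). Signal recognition particle receptor (Mcavernosa05941), which docks ribosomes at the endoplasmic reticulum, was detected in 0 of 8 transplants and 5 of 10 shallow controls (adjusted p = 0.0257), and a proteasome gene (Mcavernosa08050) in 0 of 8 transplants and 4 of 7 mesophotic controls (adjusted p = 0.0386). At time 6 edgeR called 68 isogroups against mesophotic controls (29 higher, 39 lower, and 33 and 29 by RLE), 87 against shallow controls (67 higher, 20 lower) and 20 in the change from baseline (10 each way). In each of these limma called 0 (4.12%, 4.08% and 4.36% of isogroups at an unadjusted p under 0.05). Leaving out EFGB_transplant_six replicate 1 took the 68 to 0 and the 87 to 27 (its title carries the date of time 12), and leaving out WFGB_mesophotic_six replicate 2 took the 20 to 6. Before transplantation the 2 mesophotic arms had 0 edgeR calls (8.41% at an unadjusted p under 0.05, 59 by DESeq2, 0 by limma). For the symbiont, edgeR called 0 isogroups against mesophotic and shallow controls at times 6 and 12 (1, 4, 11 and 0 at an unadjusted p under 0.05, 6, 18, 8 and 0 by DESeq2, and 18, 0, 7 and 17 by limma). At most 2 symbiont libraries per arm had passed the count minimum. The mesophotic arm held 1 at either time and the shallow arm 1 at time 12, so these calls rest on single libraries.

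The symbiont took a median of 2.24% of counts in transplants at time 12, 11.1% in mesophotic controls and 8.71% in shallow controls. The difference in log2 odds was -2.69 against mesophotic controls (exact permutation p = 0.0446, n = 6 and 6) and -1.94 against shallow controls (exact permutation p = 0.0454, n = 6 and 9), and neither passed the correction over 4 comparisons (adjusted p = 0.0908). Both passed it without WFGB_transplant_twelve replicate 1 (-3.74 and -2.52, adjusted p = 0.0327 for both). At time 6 the medians were 6.26%, 4.49% and 3.37%, and the differences 0.02 and -0.06 (exact permutation p = 0.973 and 0.904, n = 8 against 7 and 10). Measured from each colony's own baseline, a comparison added after the data had been seen, the share of transplants fell by 3.78 more than that of mesophotic controls to time 12 (log2 odds, exact permutation p = 0.00893, adjusted over 2 times p = 0.0179, n = 4 and 6). It fell in 4 of 4 transplants, whose median went from 25.4% to 2.24%, and in 2 of 6 controls (10.7% to 11.1%). To time 6 the difference was -0.79 (exact permutation p = 0.244, n = 8 and 7). By then the share had fallen in 7 of 8 transplants (median 11.2% to 6.26%) and in 6 of 7 mesophotic controls (10.2% to 4.49%). The share thus also changed between collections without transplantation. In 2 of the 4 transplants followed to time 12, a single isogroup held 93.8% and 93.2% of the symbiont counts. These were EFGB_transplant_twelve replicate 1 and WFGB_transplant_twelve replicate 1, so that their shares rest mostly on that isogroup. In WFGB barcode run 4 the median share was 29.6% in mesophotic and 22.6% in shallow natural libraries. In runs 5 to 7 it was at most 10.6%. The baselines of WFGB_transplant_twelve replicates 1 and 3 and of 2 of the 6 controls were in run 4. Barcode run was not tested apart from the fall. Among the 46 timed libraries the share fell with the log2 library total (Pearson r = -0.527, permutation p = 0.00014; Spearman rho = -0.538; r = -0.534 without the 2 libraries farthest from the median). Transplants at time 12 had a median total of 400196, mesophotic controls 54589.5 and shallow controls 127828. With the log2 total as a covariate the difference at time 12 was -2.28 ± 1.27 and -1.70 ± 0.88 (permutation p = 0.108 and 0.0801), and in the change from baseline -3.32 ± 1.77 (permutation p = 0.110).

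**Figure D3:**
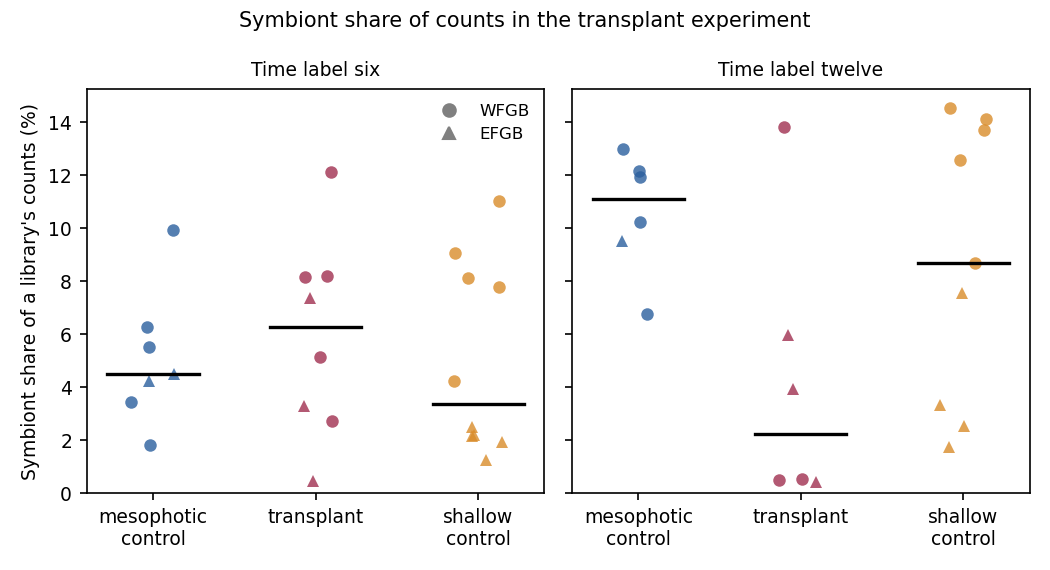
Share of a library's counts that came from Cladocopium isogroups (percent) in transplants, mesophotic controls and shallow controls at times 6 and 12, with 1 mark per library (circles WFGB, triangles EFGB) and black lines at the medians. At time 12 the median was 2.24% in transplants and 11.1% in mesophotic controls.

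A depth score asked whether transplants moved towards the natural shallow profile. It was the mean log2 CPM of 160 host isogroups higher in shallow colonies outside the experiment minus that of 70 higher in mesophotic ones. Each was called by edgeR for the mean over sites, with the same sign at every site. The score averaged 0.18 in natural shallow and -0.61 in natural mesophotic libraries, a gap fixed by choosing the isogroups from these same libraries. Over all natural libraries chance was not excluded for that edgeR comparison (26 of 100 regroupings gave as many calls). An unchanged score thus cannot tell whether transplants moved towards a shallow profile. From baseline to time 6, transplants changed by 0.15 more than mesophotic controls (exact permutation p = 0.467, n = 7 and 7), and to time 12 by -0.16 (exact permutation p = 0.548, n = 3 and 6). With the top 100 isogroups each way the changes were 0.29 (exact permutation p = 0.0754) and 0.47 (0.0714), and with isogroups called by limma 0.81 (0.371) and 0.31 (0.810). As sets in camera, the 2 groups of depth isogroups gave adjusted p of 0.319 or more for transplants against mesophotic controls at times 6 and 12 and at baseline. The other transplant comparisons were not tested in this way.

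**Figure D4:**
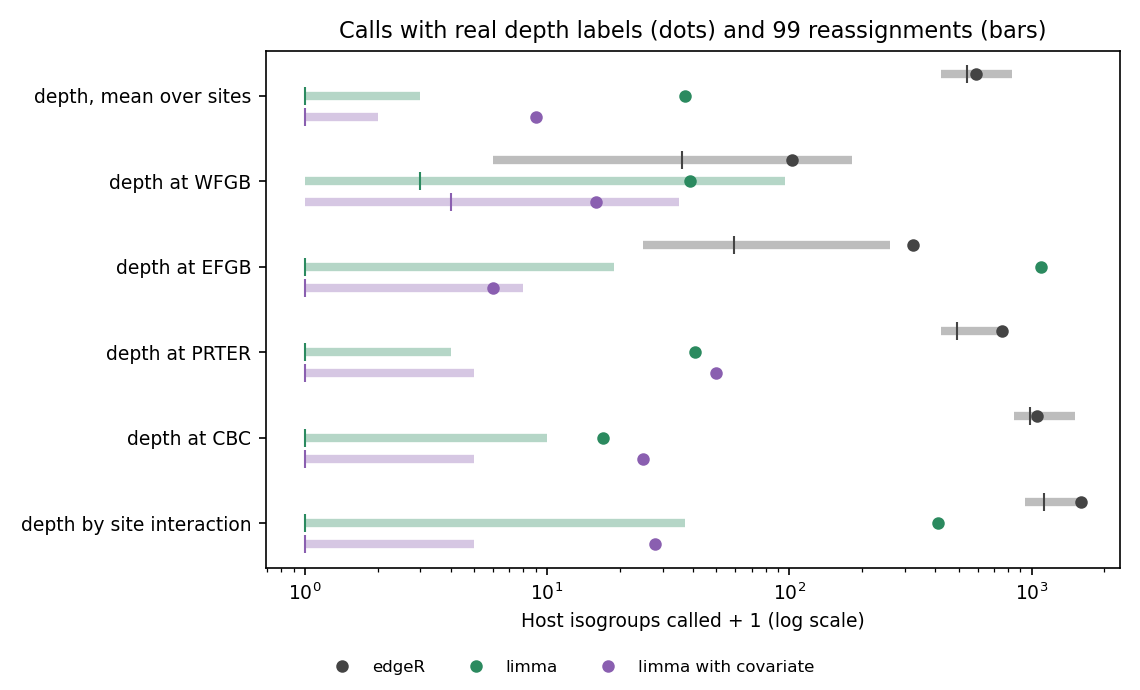
Host isogroups called for each depth comparison (count plus 1, log scale) by edgeR, limma and limma with a covariate, with dots for the real labels, bars for the range over the other regroupings of the libraries and ticks for their median. For the mean over sites edgeR called 590 with the real labels and up to 829 with reassigned ones, and limma 36 and up to 2.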

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

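Predictions for the barcode run, library size and detection tests of the PRTER share, for the share of CBC calls in scarcely detected isogroups, for capped counts over reassigned labels and for detected isogroups within campaigns that hold both depths were written before their results were seen. Those for the regroupings of libraries and the other tests were written after. As alternatives, the limma models, the capped counts, the removal of X-14, the split by campaign, the change of share from baseline and its adjustment for library total were chosen after the data had been seen.

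The difference in symbiont share between depths differed between sites (F = 7.53, permutation p = 9.0e-05, n = 119 and 146), from 1.05 at PRTER to -0.44 at EFGB in log2 odds. edgeR called 43.2% of the host isogroups tested and 40.5% of the symbiont isogroups for a depth difference that differed between sites. The symbiont share of transplants changed from baseline to time 12 by -3.78 in log2 odds beyond the change of mesophotic controls (exact permutation p = 0.00893, n = 4 and 6). It lay between -4.58 and -2.72 with each colony left out (the extremes without WFGB_transplant_twelve replicates 1 and 3, exact permutation p of 0.0238 or less). With the change of log2 library total as a covariate it was -3.32 ± 1.77 (permutation p = 0.110), and log2 totals rose by 3.34 in transplants against a change of -0.74 in controls. Barcode run was not tested apart from this change of share. EFGB_shallow_six replicate 1 had 2498 host isogroups detected and the nearest of its 4 companions 1617, a gap of 0.723 of the range of that group. It was the only library to stand apart in this way in 7 groups of 4 or 5 libraries, each tested on 3 measures at both ends. Chance alone picks about 1 in 20 groups on each measure, so that 1 such library is no more than expected.

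The first pattern is that edgeR called about as many host isogroups between depths with labels reassigned within sites as with the real labels, 590 for the mean over sites against up to 829. At CBC, the only site examined for this, scarcely detected isogroups do not account for most calls. There 15.1% of the 1049 calls, against 9.05% of the isogroups tested, were detected in under 10% of CBC libraries. The median isogroup was detected in 19.0% of CBC libraries among the calls and in 25.9% among those tested. Single libraries with very high counts may account for some of the calls: with counts capped, the median number over reassigned labels was 166, against 539 without the cap. The calls with the real labels also fell, from 15.9% to 6.41% of isogroups, and 12 of 100 regroupings still gave as many, up to 438, so that the pattern itself stayed. Which property of the counts gives it was not settled, and no biological explanation was tested, since reassigned labels carry no depth.

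The second pattern is that limma called 1090 host isogroups between depths at EFGB, 1052 of them higher in shallow libraries. With the number of detected isogroups as a covariate the count was 5, and without the X-14 libraries, all shallow, it was 36. A difference in library complexity between collections is a candidate explanation that both counts fit. Leaving out X-14 also took away 26 of 41 shallow libraries, however, and lost power was not tested apart from it. The scaffold protein AHNAK had -3.52, -2.05 with the covariate and -2.73 without X-14, a ferritin-like gene -2.88, -1.93 and -2.51, and Grp94 -2.72, -2.34 and -3.74. Between depths at EFGB log2 detected isogroups differed by -0.66 (permutation p = 0.00026, n = 21 and 41), and within the campaigns that hold both depths by -0.36 (permutation p = 0.129, n = 20 and 15). The 26 X-14 libraries had a median of 4343.5 detected host isogroups, and those campaigns 1808.5 at mesophotic and 2721 at shallow depth. A depth difference in the number of expressed genes cannot be told apart from collection, because X-14 holds no mesophotic library.

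The third pattern is the higher symbiont share in mesophotic libraries at PRTER. The tables argue against barcode run, library size and detection as the whole cause: the lowest difference within a run was 0.82 (permutation p = 0.00609), and the difference was 1.01 ± 0.17 with log2 total and 1.05 ± 0.17 with log2 detected host isogroups as a covariate, against 1.05 without. Collection campaign stays open, because the difference was 0.12 within VIII-13 (exact permutation p = 0.663, n = 22 and 5) and 1.29 among coded titles (permutation p = 1e-05, the smallest possible, n = 19 and 26). Depth itself, through more symbiont RNA or less host RNA per colony, may account for it. With the campaign label held fixed, a depth difference was seen among coded titles and not within VIII-13, which had 5 shallow libraries. Coded titles carry no date, so they need not be a single collection.

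Labels were reassigned 100 times, depths within sites, sites within depths and the arms of whole colonies within sites, and brackets give the percent of isogroups tested that was called with the real labels, the number of regroupings with as many calls or more (the real one included) and the highest percent of the others. Fewer than 5 such regroupings was the rule for calling chance excluded, with no correction over these tests. Title campaigns were not kept together when depths were reassigned. For edgeR on host isogroups, chance was excluded at EFGB (8.75%, 1 and 6.99%), PRTER (20.4%, 1 and 20.2%), depth by site (43.2%, 1 and 41.9%) and between sites (61.3%, 1 and 27.8%). By the rule it was also excluded at WFGB (2.75%, 2 and 4.86%), though another regrouping gave more calls. Reassigned labels still gave a median of 493 calls at PRTER and 1124 for depth by site, against 757 and 1598 with the real labels. With counts capped the real labels gave 324 calls at PRTER, and 2 regroupings as many, up to 415. For depth by site they gave 715, and 3 regroupings as many, up to 896. At EFGB the 8.75% became 2.75% with campaign as a covariate. At WFGB, however, with counts capped edgeR made 1 call and 28 regroupings gave as many, and its 2.75% became 0.054% with barcode run, 0.108% with campaign or RLE and 0.134% with all libraries kept. Chance was not excluded for the mean over sites (15.9%, 26 and 22.4%), CBC (28.3%, 27 and 40.8%) or EFGB minus WFGB (7.32%, 41 and 14.5%). In the experiment chance was excluded at time 12 against shallow controls (8.30%, 1 and 4.75%) and in the change to time 12 (3.66%, 1 and 1.79%). The first of these became 0 with 1 library left out, and with a block for colony edgeR called 0 in the second (606 at an unadjusted p under 0.05; 0 by limma, 13.5% by DESeq2). It was not at time 6 against mesophotic controls (1.90%, 68 and 25.4%), against shallow controls (2.43%, 74 and 21.4%) or in the change (0.559%, 86 and 12.6%), at time 12 against mesophotic controls (0.112%, 6 and 5.73%) or at baseline (0%, 100 and 0.0279%). For edgeR on symbiont isogroups it was excluded at PRTER (18.5%, 1 and 9.37%), depth by site (40.5%, 1 and 36.6%) and between sites (73.4%, 1 and 58.4%). By the rule it was also excluded at CBC (32.9%, 4 and 35.7%), though another regrouping gave more calls. It was not excluded for the mean (9.15%, 33 and 13.5%), WFGB (0%, 100 and 0%), EFGB (23.1%, 10 and 26.8%) or EFGB minus WFGB (16.3%, 6 and 20%). Why some splits gave several times the real count was not tested, and structure among the libraries other than the labels is 1 candidate. For a simulated host depth difference, without such structure, 48.9% of edgeR's calls were false.

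In the same order, for limma on host isogroups chance was excluded for the mean (0.543%, 1 and 0.0302%), EFGB (16.4%, 1 and 0.272%), PRTER (0.603%, 1 and 0.0453%), CBC (0.241%, 1 and 0.136%), depth by site (6.22%, 1 and 0.543%), between sites (72.2%, 1 and 0.121%) and EFGB minus WFGB (25.7%, 1 and 0.0151%). It was not excluded at WFGB (0.573%, 5 and 1.43%). Without the X-14 libraries, all shallow, limma called 3 isogroups for the mean, 36 at EFGB and 16 for depth by site. These regroupings do not keep collection apart from depth. With the covariate chance was excluded for the mean (0.121%, 1 and 0.0151%), PRTER (0.739%, 1 and 0.0603%), CBC (0.362%, 1 and 0.0603%), depth by site (0.407%, 1 and 0.0603%), between sites (13.5%, 1 and 0.0302%) and EFGB minus WFGB (0.226%, 1 and 0.0754%). By the rule it was also excluded at WFGB (0.226%, 3 and 0.513%) and EFGB (0.0754%, 3 and 0.106%), though another regrouping gave more calls in each. For limma on symbiont isogroups it was excluded for PRTER (6.58%, 1 and 0.700%), between sites (17.5%, 1 and 1.82%) and EFGB minus WFGB (5.6%, 1 and 1.26%). By the rule it was also excluded for the mean (0.280%, 4 and 4.76%) and WFGB (4.76%, 3 and 6.58%), though another regrouping gave more calls in each. It was not excluded at EFGB (0.140%, 20 and 0.700%) or for depth by site (0.840%, 7 and 2.66%). With the covariate it was excluded at WFGB (2.66%, 1 and 2.38%), PRTER (4.06%, 1 and 0.420%), between sites (15%, 1 and 1.4%) and EFGB minus WFGB (0.560%, 1 and 0.140%), and not at EFGB (0.140%, 26 and 0.840%). In the experiment limma called 1 host isogroup at time 12 against mesophotic controls (0.0140%, 30 and 0.251%) and 1 against shallow controls (0.0140%, 29 and 0.209%), where chance was not excluded. Nor was it against mesophotic controls with the covariate (0.0140%, 31 and 0.0838%), whereas it was against shallow controls (0.0978%, 1 and 0.0838%). Of the gene lists, as many as the real number passed for the host mean (1 list, 12 and 1), the host at WFGB (2, 5 and 2) and the symbiont at EFGB (1, 5 and 2), so that chance was not excluded for any of the 3. On limma values 1 list each passed for the symbiont at WFGB (11 and 1), EFGB (carbon fixation, 3 and 1) and PRTER (2 and 1). The rule for excluding chance was met at EFGB and PRTER, but reassigned labels also gave 1 list there. The count takes in any list, and the list that passed was not tested by itself.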

How the results depend on the processing

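The limma models, the minimum of 5000 symbiont counts, capped counts, the removal of the X-14 libraries, camera on limma, the change of share from baseline and the log2 total covariate were chosen after the data had been seen. So were the wider ribosomal list, limma genes for the score, the change of share without each colony and a block for colony with all libraries kept. The other alternatives were fixed before. Over alternatives other than left-out libraries, 189 counts of isogroups changed by more than 1.5 times. Of the values for isogroups named by rule, 857 kept their side of the threshold, 659 lost the call and 7 gained one. Another 33 changed sign where the reported or the alternative setting gave a call. Sign changes without a call under either setting were not counted apart from the 857. Among share values 36 kept their side of the threshold, 2 lost a call and 1 gained one, and among gene lists 5 lost and 2 gained one. The depth score and the depth sets kept their side of the threshold in each alternative run. Where no reason is given, the cause was not tested. Low symbiont counts were one limit: 199 libraries fell under 20000 symbiont counts and at most 2 per arm and time were left in the experiment.

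Calls are given here as percent of the isogroups tested under each setting, because the settings test different numbers of them. With the reported settings edgeR called 15.9% of host isogroups for the mean over sites and 2.75%, 8.75%, 20.4% and 28.3% at WFGB, EFGB, PRTER and CBC. It called 43.2% for depth by site, 61.3% between sites and 7.32% for EFGB minus WFGB. In the experiment it called 1.90%, 2.43% and 0.559% at time 6 (against mesophotic controls, against shallow controls and in the change) and 0.112%, 8.30% and 3.66% at time 12. For the symbiont it called 9.15% for the mean, 0%, 23.1%, 18.5% and 32.9% at the 4 sites, 40.5% for depth by site, 73.4% between sites and 16.3% for EFGB minus WFGB.

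With RLE, edgeR called 9.59% of host isogroups for the mean, 0.108% at WFGB, 4.43% at EFGB, 17.2% at CBC, 27.4% for depth by site and 2.81% for EFGB minus WFGB. At time 12 it called 9.53% against mesophotic controls, 13.7% against shallow controls and 10.4% in the change. Without a filter, which tests more isogroups, the host values were 12%, 14%, 23.8%, 25.3% and 19% for the mean, WFGB, EFGB, PRTER and CBC. They were 39.4% for depth by site, 51.2% between sites and 17.8% for EFGB minus WFGB. In the experiment they were 3.01%, 3.90% and 1.79% at time 6 and 0%, 0.79% and 2.0% at time 12. For the symbiont they were 0.423% for the mean, 0% at EFGB, 31.1% at PRTER, 1.53% at CBC, 6.17% for depth by site, 15% between sites and 0.0955% for EFGB minus WFGB. With title campaign as a covariate edgeR called 7.16% of host isogroups for the mean, 0.108% at WFGB and 2.75% at EFGB, and of symbiont isogroups 0% for the mean, 0% at EFGB and 16.6% for depth by site. With barcode run it called 0.054% of host isogroups at WFGB and 4.40% for EFGB minus WFGB, and of symbiont isogroups 3.05% for the mean, 0% at EFGB and 3.27% for EFGB minus WFGB. With capped counts the host values were 6.41%, 0.028%, 4.71%, 9.08% and 11.1% for the mean and the 4 sites, 20.03% for depth by site and 2.80% for EFGB minus WFGB.

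With all libraries kept, edgeR called 0.134% of host isogroups at WFGB and 3.85% for EFGB minus WFGB, 1.46%, 1.46% and 0.199% at time 6 and 0.0662%, 0.132% and 1.23% at time 12. For the symbiont it called 4.70% at WFGB, 12.1% at PRTER, 32.2% at CBC, 5.63% and 5.63% at time 6 and 4.93% and 9.86% at time 12. With a minimum of 100000, which keeps fewer libraries, it called 0% of host isogroups at WFGB, 22.1% at EFGB and 14.9% for EFGB minus WFGB, 0% and 0.0148% at time 6 against mesophotic and shallow controls and 0% for both at time 12. Each site alone, with fewer libraries per estimate of spread, gave 0%, 1.21%, 5.05% and 0% of host isogroups at WFGB, EFGB, PRTER and CBC, and 0%, 3.33% and 0% of symbiont isogroups at EFGB, PRTER and CBC. DESeq2 called 10.4% of host isogroups at WFGB, 14.9% at EFGB, 39% for depth by site and 61.8% between sites. It called 4.23%, 7.15% and 2.85% at time 6, 16.1%, 19.1% and 13.5% at time 12 and 1.73% at baseline. For the symbiont it called 20.2% for the mean, 9.76% at WFGB, 16.7% at CBC, 12.9% for depth by site and 22.2% between sites, and 1.62% and 4.86% at time 6 and 2.16% at time 12 against mesophotic controls. Without X-14 edgeR called 0.0483% of host isogroups at WFGB and 2.73% for EFGB minus WFGB. For the symbiont it then called 0.457% for the mean, 0% at EFGB, 37.6% at PRTER, 28.8% at CBC, 66.8% between sites and 0% for EFGB minus WFGB. WFGB alone gave 0.0344%, 0% and 0% at time 6 and the same at time 12, and a block for colony 0% in both changes.

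On host isogroups limma called 0.543%, 0.573%, 16.4%, 0.603% and 0.241% for the mean, WFGB, EFGB, PRTER and CBC. It called 6.22% for depth by site, 72.2% between sites and 25.7% for EFGB minus WFGB, 0% at time 6 in each comparison and 0.014%, 0.014% and 0% at time 12. With the covariate the same values were 0.121%, 0.226%, 0.0754%, 0.739% and 0.362%, then 0.407%, 13.5% and 0.226%, then 0% at time 6 and 0.014%, 0.0978% and 0% at time 12. Without X-14 limma called 0.0526%, 0%, 0.631%, 0.544% and 0%, 0.281% for depth by site and 14.8% for EFGB minus WFGB. On symbiont isogroups limma called 0.28%, 4.76%, 0.14%, 6.58% and 0%, then 0.84%, 17.5% and 5.6%, and in the experiment 4.13% at time 6 against mesophotic controls and 1.61% and 3.90% at time 12. With the covariate these were 0%, 2.66%, 0.14%, 4.06% and 0%, then 0%, 15% and 0.56%, 1.15% at time 6 and 2.75% at time 12 against shallow controls. Without X-14 they were 0.145%, 0.289%, 0%, 6.65% and 0.145%, then 0.145%, 7.37% and 0.145%. With a minimum of 5000 limma called 0.469% for the mean, 9.38% at WFGB, 0.938% at EFGB, 0.234% at CBC, 13% for depth by site, 4.69% for EFGB minus WFGB and 0.102% against either control at time 12. With the covariate as well these were 0.821%, 0.117%, 0.469%, 0.234%, 1.06% and 0%, and 0.102% at time 12 against shallow controls.

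Innate immunity lost its call with an estimated correlation (adjusted p = 0.444), on limma (0.0519), with capped counts (0.0626), without a filter (0.247) and with a minimum of 100000 (0.238). Carbon fixation in the symbiont gained a call with all libraries (0.00695, where fewer isogroups and lists could be tested) and without X-14 (0.0481). The mean depth difference in share lost its call in libraries of at least 100000 counts (0.20, adjusted permutation p = 0.367) and without X-14 (0.29, 0.0814). The share at time 12 gained a call as a change from baseline (-3.78). With the change of log2 total as a covariate the estimate was -3.32 ± 1.77, without a call (permutation p = 0.110). Log2 totals changed by 3.34 in transplants and -0.74 in controls, so that arm and total can hardly be told apart. The permutation test also differed, with residuals reassigned in place of arms within sites.

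With 1 timed library left out, host calls ranged at time 6 from 0% (without EFGB_transplant_six replicate 1) to 3.92% (WFGB_mesophotic_six replicate 4) against mesophotic controls and from 0.794% (EFGB_transplant_six replicate 1) to 10.4% (WFGB_shallow_six replicate 1) against shallow controls. In the change they ranged from 0.175% (WFGB_mesophotic_six replicate 2) to 1.57% (WFGB_transplant_six replicate 4). At time 12 they ranged from 0% (EFGB_transplant_twelve replicate 1 and others) to 0.147% (EFGB_transplant_six replicate 1) and from 0% (EFGB_transplant_twelve replicate 2 and EFGB_shallow_twelve replicate 3) to 10.2% (EFGB_transplant_six replicate 1). In the change they ranged from 0.56% (WFGB_transplant_twelve replicate 3) to 5.03% (WFGB_transplant_six replicate 2). At baseline they stayed at 0. Symbiont calls ranged from 0% to 0.304% and from 0% to 0.608% at time 6 and from 0% to 1.64% and from 0% to 0.608% at time 12. The share difference at time 12 ranged from -3.74 to -2.09 against mesophotic controls and from -2.52 to -1.37 against shallow controls (extremes without WFGB_transplant_twelve replicates 1 and 3). Its unadjusted exact permutation p passed 0.05 against mesophotic controls without any of WFGB_mesophotic_twelve replicates 1 to 5, EFGB_mesophotic_twelve replicate 1 or WFGB_transplant_twelve replicates 2 and 3. Against shallow controls it did so without EFGB_transplant_twelve replicate 2, WFGB_transplant_twelve replicates 2 and 3, WFGB_shallow_twelve replicates 1 to 5 or EFGB_shallow_twelve replicates 2 to 4. At time 6 it ranged from -0.24 to 0.42 and from -0.41 to 0.34.

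Some isogroups named by rule and called with the reported settings changed sign, none of them past the threshold in the new direction. Sign changes of isogroups without a call are not listed. For the mean over sites they were Mcavernosa28568 (DESeq2 -0.51), Mcavernosa23086 (limma -0.22, with covariate -0.20), Mcavernosa06196 (limma -0.025) and Mcavernosa15401 (campaign 0.14). Mcavernosa25260 (barcode run -0.20, DESeq2 -1.43) and Mcavernosa09571 did so in 3 limma fits, the plain one, that with the covariate and that without X-14 (-0.11, -0.15 and -0.14, and -0.21, -0.12 and -0.21). So did Mcavernosa24180 (-0.063, -0.019 and -0.11, with a minimum of 100000 -0.17 and with campaign -0.19). The rest were Mcavernosa27370 (0.075 with covariate, 0.12 without X-14), Mcavernosa29568 (0.00019 with covariate), Mcavernosa04107 (DESeq2 -0.44, limma -0.10), Mcavernosa00289 (limma -0.039) and Mcavernosa06771 (DESeq2 -0.83, limma -0.12). In other comparisons they were Mcavernosa13577 at PRTER (DESeq2 1.0) and Mcavernosa13272 for EFGB minus WFGB (limma -0.20, without X-14 -0.75). Mcavernosa14973 against shallow controls at time 12 had -0.38 without EFGB_transplant_twelve replicate 2 and up to 9.60 without EFGB_shallow_six replicate 4. In the symbiont Cladocopium214787 changed sign at CBC (DESeq2 -0.11). With a minimum of 5000 so did Cladocopium117232 at EFGB (0.068, with covariate), Cladocopium251153 at CBC (0.032) and Cladocopium223611 for EFGB minus WFGB (0.036, with covariate).

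Several alternatives could not be run. A minimum of 100000 left too few symbiont libraries and, for the host, no change or baseline comparison. The symbiont changes and baseline had too few libraries past the minimum. With all libraries kept edgeR called 4, 10 and 0 symbiont isogroups there, and with a block for colony 0 and 0. A symbiont depth score was not computed.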

Other observations

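The values below were looked up after the data had been seen, and the pairing of colonies and the transplant library totals were not part of the planned comparisons. Over all libraries the largest symbiont isogroup held up to 94.9% and the largest host isogroup up to 44.8%.

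The number of detected host isogroups fell with the host total over all libraries (Pearson r = -0.538 and Spearman rho = -0.551 on log2 values, permutation p = 1e-05, the smallest possible), and r was -0.576 without the 2 libraries farthest from the median. Within sites r was -0.539 at WFGB (rho -0.317), -0.651 at EFGB (-0.663), -0.364 at PRTER (-0.252) and -0.362 at CBC (-0.189, permutation p = 0.14). The symbiont share also fell with the library total within each site by Pearson r (-0.355, -0.413, -0.268 and -0.523 in the same order). Spearman rho was -0.306, -0.466, -0.193 (permutation p = 0.104) and -0.505. With log2 total as a covariate the depth difference in share was 0.36 at WFGB, -0.32 at EFGB, 1.01 at PRTER and 0.06 at CBC (adjusted permutation p = 0.228, 0.228, 4e-05 and 0.740).

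Host profiles of the 58 pairs of libraries that share a colony tag correlated across genes with a mean r of 0.0178. Arm and time means, site, log2 host total and log2 detected isogroups had been removed. The 1154 pairs of different colonies at the same site had a mean r of -0.0307. Of the 58 pairs 3 were above 0.1, and genes are not independent replicates.

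In the median host isogroup, 40.2% of all counts lay in its 3 richest libraries, and in the median symbiont isogroup 33.2%. The highest correlation between any 2 host libraries was 0.612 across genes, against a median of 0.376. Proteasome and ubiquitin in the symbiont at PRTER passed only on the limma fit (lower in mesophotic libraries, 0 of 6 members called, median -0.27, camera adjusted p = 0.0289).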
